A study of Mus musculus with 22 samples.

How the data were processed

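The deposited tables were used as given by the authors, and no reads were aligned again. Per the labels, libraries were made with the NextFlex small RNA V3 kit from the RNA of HDL. FastQC, cutadapt, Bowtie and the mouse genome mm9 are named per the submitters' processing notes, with no versions, order or settings given in the sources used here, and the deposited readme names the TIGER pipeline. The readme divides bacteria into those of the human microbiome and those of the environment. Tables list features by name, and the genome reference available here was of another version than mm9, so no coordinates were used.

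The 10 tables compared here (miRNA, tRNA, rRNA, snRNA, snoRNA, other host RNA, human-microbiome bacteria, environmental bacteria, fungi, algae) hold RPM computed by the authors, and their values showed the denominator to be all reads of the library, with short and unmapped reads included. The table of all categories holds estimated counts (expected counts) made by the authors with the TIGER pipeline as deposited. It gave the class totals, scaled here to RPM with all reads of the library. Its non-host categories summed to more than the reads mapped to non-host, so a read can count in several of them. The remaining table holds the count of reads in 5 stages that do not overlap, made by the authors with the same pipeline as deposited. The planned count tests needed whole reads, which the RPM did not give in every table. RPM were turned into estimated reads with the library totals, rounded, and tested with edgeR and DESeq2, a step chosen after seeing the data. Of the values above 0 and under 100 reads, 95.7% to 99.4% in the 6 host tables and 24.7% in the table of human-microbiome bacteria came within 0.05 of a whole read. Estimated reads are thus close to whole reads in the host tables for low values, and less so in the bacterial tables.

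Libraries held 4658603 to 13223631 reads in GF of set 1, 9431349 to 10258499 in SPF of set 1, 15909508 to 28684541 in GF of set 2 and 16289809 to 20115417 in SPF of set 2, with 19730 to 541172 reads of host miRNA. No pair of libraries held identical values. The mapping between table columns and sample labels was made by group only, since the columns carry no mouse or cohort number. The cohort term of the models was the naming set of the columns, whose sizes equal those of the cohorts in the labels.

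Features with a mean of at least 1 RPM were tested on log2(RPM + 1) with limma 3.58.1 (linear model with set and group, eBayes with trend and robust), with Benjamini-Hochberg adjustment within each table and a threshold of 0.05. Fold changes are on the log2(RPM + 1) scale, which understates differences of low features. Class totals and the ratio of non-host to host reads were compared by a two-sided exact permutation test over all 26400 splits of the libraries within sets, with intervals from inverting the test and adjustment over the 14 classes. Lists with at least 3 tested members (30 of 67) were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted within each table. Members were taken from general knowledge and fixed before the data were examined. The other tools were edgeR 4.0.16 and DESeq2 1.42.0 under R 4.3.3, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

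Names of genes and categories were chosen by rule: features called in limma with the same sign in both sets (there were 0), the 5 most abundant miRNAs, the 3 most abundant categories per bacterial table and the 2 most abundant of each other table, examples from lists among the 2 members with the smallest p, and where nothing was called the 2 features with the smallest p. Alternatives fixed before the data were examined covered the offset added before the log, the filter on low values, the set term, the scaling, the variance model, weights per library, each set alone, each library left out, and for class totals rank statistics and other denominators. Libraries that stood apart in their groups were left out in an alternative chosen after seeing the data, as were the permutation tests of lists, the test of classes by set and the comparison of the sets. The volume of plasma, the RNA input and the batch of the kit were not given in the sources used here.

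With 6 SPF mice, simulated 4-fold changes were found by limma for 68.4% of miRNAs, 71.9% of tRNAs and 95.5% of human-microbiome bacteria, and simulated 2-fold changes for 17.1% of miRNAs. These changes were added on the log2(RPM + 1) scale with noise independent between features, so the shares are too high for features near 1 RPM. False calls made up 1.9% (environmental bacteria) to 19.05% (other host RNA) of the simulated calls. With independent noise these shares do not hold where features vary together. Splits of the real libraries within sets, other than the real groups, called up to 111 environmental bacteria. A 4-fold difference of a class total gave an unadjusted exact permutation p under 0.05 in 98.3% of simulations for miRNA and 82.8% for tRNA. The real class totals were judged on p adjusted over all classes, which is stricter. These shares can therefore be too high for the test as it was used.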

Results

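High-density lipoprotein (HDL) is the plasma particle that returns cholesterol to the liver, and it also carries small RNA. Small RNA on HDL was sequenced here from germ-free (GF) 129SvEv mice, which are raised without microbiota, and from specific-pathogen-free (SPF) mice of the same facility and age. GF was the case and SPF the control, so each difference below is GF minus SPF, with values in RPM (reads scaled to all reads of the library). There were 22 libraries, 16 GF and 6 SPF, each from 1 mouse per the labels. The mice came in 2 cohorts per the labels, and the library names in the deposited tables fall into 2 naming sets of the same sizes: set 1 with 7 GF and 3 SPF libraries, set 2 with 9 GF and 3 SPF. The names do not state the cohort, so the groups are called set 1 and set 2, and every model held the set constant. The choices of test, threshold, filter and list were fixed before the data were examined, except where stated.

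Libraries from HDL of GF mice held reads assigned to bacteria, fungi and algae. The permutation tests of the class totals did not separate their amounts from those of SPF mice. No blank preparation was among the libraries, so whether HDL carried these reads was not tested. Reads assigned to environmental bacteria averaged 164905 ± 97845 RPM in GF (SD, n = 16) and 135938 ± 117714 RPM in SPF (SD, n = 6). Reads assigned to bacteria of the human microbiome averaged 77214 ± 47857 RPM in GF (SD, n = 16) and 77437 ± 56695 RPM in SPF (SD, n = 6). On the log2(RPM + 1) scale the differences were 0.37 (95% interval −0.44 to 1.18) and 0.05 (−0.59 to 0.69). Fungi differed by 0.06 (−0.26 to 0.39), algae by −0.11 (−0.57 to 0.34) and viruses by 0.20 (−0.33 to 0.71). Reads matching small RNAs of other species differed by 0.12 (−0.85 to 1.11) for miRNA, −0.05 (−0.98 to 0.88) for tRNA and −0.15 (−0.35 to 0.06) for rRNA.

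Host classes on HDL did not separate the groups either. Host miRNA averaged 17779 ± 18920 RPM in GF (SD, n = 16) and 20288 ± 20509 RPM in SPF (SD, n = 6), a log2 difference of 0.09 (95% interval −0.88 to 1.07). Differences were taken within sets on the log scale, so pooled means, which set 1 dominates for host RNA, can point the other way, as they did here. Host tRNA fragments differed by −0.36 (−1.71 to 0.98), rRNA by −0.08 (−1.11 to 0.97), snRNA by −0.45 (−1.53 to 0.64), snoRNA by −0.13 (−1.12 to 0.85) and the remaining host RNA by 0.29 (−0.57 to 1.17). In the 14 classes the two-sided exact permutation test within sets gave an adjusted p of 0.917 throughout, and the smallest unadjusted exact p was 0.160, for rRNA of other species. The intervals of human-microbiome bacteria, fungi, algae, viruses and non-host tRNA and rRNA lay within a 2-fold change, whereas those of environmental bacteria, non-host miRNA and every host class reached beyond it. The ratio of non-host to host reads differed by −0.03 (−0.89 to 0.81, two-sided exact permutation p = 0.941). Its median was 2.99 in GF and 3.06 in SPF of set 1, and 22.9 in GF and 22.5 in SPF of set 2.

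**Figure D1:**
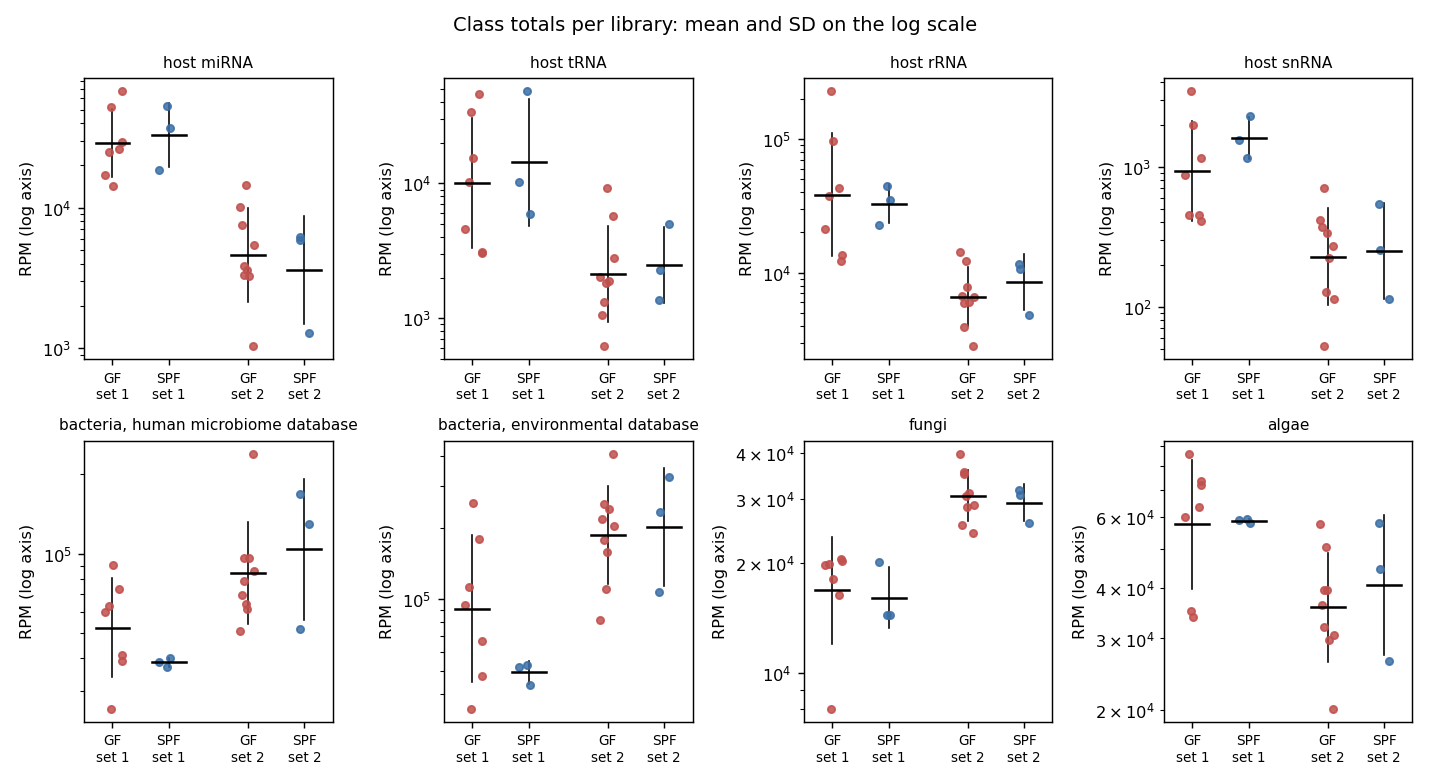
Class totals in RPM on a log axis, 1 point per library, GF in red and SPF in blue by set, with a line at the mean and a bar for the SD on the log scale. The groups overlap in every panel, and host classes sit lower in set 2.

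**Figure D2:**
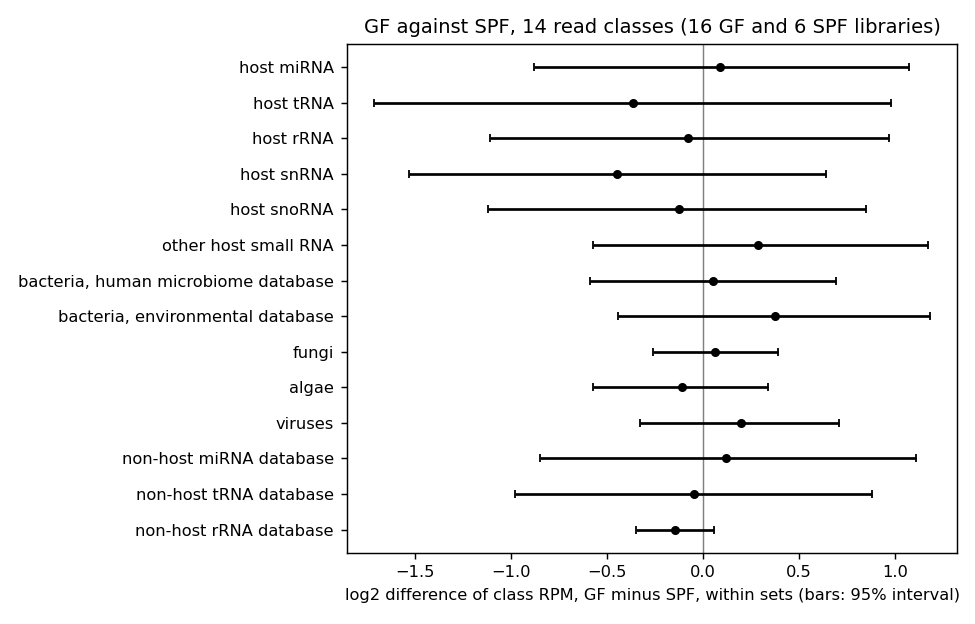
Difference GF minus SPF in log2(RPM + 1) for the 14 classes, with 95% intervals from the exact permutation test within sets. Every interval includes 0.

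Among HDL miRNAs the list with the smallest camera p was that of skeletal and cardiac muscle, whose 4 tested members were higher in GF. miR-1a-3p, the most abundant miRNA of muscle, averaged 467 ± 760 RPM in GF (SD, n = 16) and 141 ± 235 RPM in SPF (SD, n = 6), with a log2 fold change of 1.52. miR-133a-3p, encoded beside miR-1a, had a log2 fold change of 2.01, its close relative miR-133b-3p one of 1.31, and miR-206-3p, which is largely confined to skeletal muscle, one of 1.75. No single miRNA passed in limma over the 203 tested, where miR-206-3p had an adjusted p of 0.793 and miR-1a-3p one of 0.998. The 4 muscle miRNAs ranked above the other miRNAs of the table in GF (camera adjusted p = 1.16e-07; adjusted p = 0.0214 with an estimated correlation), and each of the 4 passed when limma p-values were adjusted over the list alone. Against no change fry gave an adjusted p of 0.182. Without SPF_Rep1 or SPF_Rep4 the estimated correlation no longer gave a call (adjusted p = 0.0925 and 0.102), and without SPF_Rep3 miR-206-3p passed alone (log2 fold change 2.35, limma adjusted p = 0.0378).

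In each set alone the log2 differences of the 4 muscle miRNAs were above 0. With its preset correlation camera called the list (adjusted p = 3.81e-08 for muscle in set 1 only and 0.0231 in set 2 only). However, limma called 0 of 203 miRNAs in either (8 and 4 at unadjusted p under 0.05). The correlation estimated among the 4 over all libraries was 0.66, above the preset. Using it raised the camera adjusted p over all libraries from 1.16e-07 to 0.0214. The camera values by set therefore cannot show that the call was replicated. miR-206-3p differed by 1.43 in set 1 and 2.04 in set 2, miR-133a-3p by 3.13 and 0.97, miR-133b-3p by 1.69 and 0.96, and miR-1a-3p by 2.10 and 0.97. In set 2 miR-206-3p averaged 9.85 ± 11.3 RPM in GF (SD, n = 9) and 1.14 ± 1.98 RPM in SPF (SD, n = 3). The SPF median of their own set was exceeded for miR-133a-3p by 7 of 7 GF libraries in set 1 and 7 of 9 in set 2, for miR-133b-3p by 6 of 7 and 6 of 9, and for miR-1a-3p by 6 of 7 and 5 of 9. All did for miR-206-3p, but its SPF median in set 2 was 0, so there any read counted as higher. A permutation test of the mean log2 value of the list within sets, chosen after seeing the data, gave 1.65 (95% interval 0.24 to 3.04, two-sided exact p = 0.0235, adjusted over the 30 lists 0.353). Without SPF_Rep1 the difference was 1.39 (exact permutation p = 0.0633), without SPF_Rep4 it was 1.30 (0.0749) and without SPF11 it was 1.58 (0.0532). miR-133a-3p and miR-133b-3p differ only in the last base, so the tables give no sure way to tell their reads apart.

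**Figure D3:**
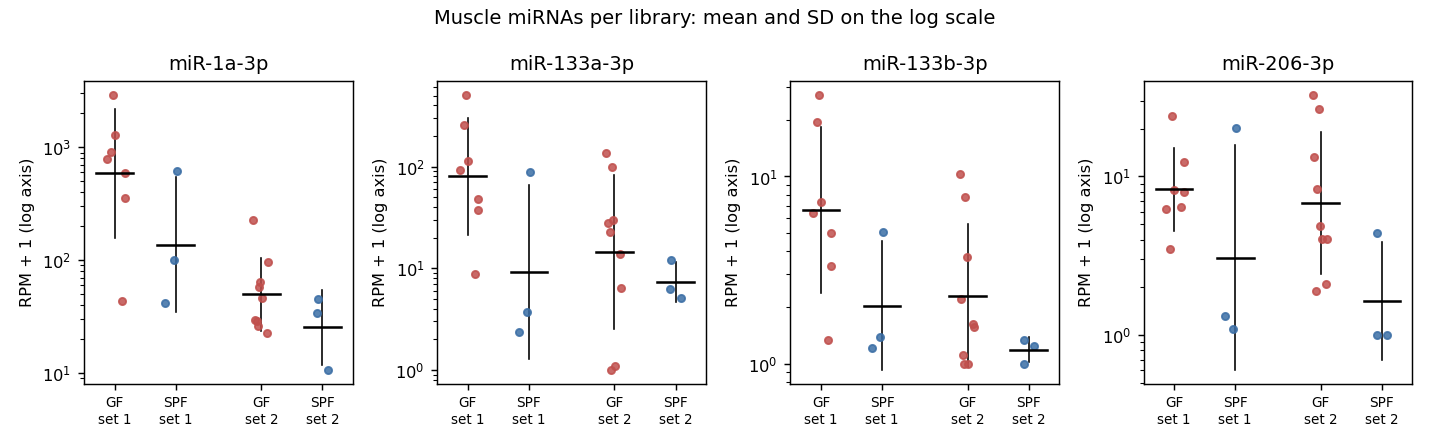
RPM + 1 of miR-1a-3p, miR-133a-3p, miR-133b-3p and miR-206-3p on a log axis, 1 point per library, GF in red and SPF in blue by set. Most GF libraries lie above the SPF median of their set, with SPF_Rep3 high among SPF.

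The most abundant miRNAs on HDL, of which several are blood-cell miRNAs, gave no call in limma. miR-486a-5p, a red-cell miRNA counted together with miR-486b-5p, averaged 4711 ± 6189 RPM in GF (SD, n = 16) and 7235 ± 8775 RPM in SPF (SD, n = 6), a log2 fold change of 0.14 within sets. By set it averaged 9311 ± 7145 RPM in GF (SD, n = 7) and 13772 ± 7992 RPM in SPF (SD, n = 3) of set 1, and 1134 ± 788 RPM in GF (SD, n = 9) and 698 ± 664 RPM in SPF (SD, n = 3) of set 2. The other abundant miRNAs were miR-92a-3p of the miR-17-92 cluster (0.12; −0.37 in set 1 and 0.58 in set 2), miR-451a, which is matured by AGO2 in red cells (−0.18; −0.50 and 0.12), miR-143-3p of smooth muscle (−0.24; 0.09 and −0.55) and the widely expressed miR-21a-5p (−0.08). miR-122-5p, the main liver miRNA, differed by 0.56 (−0.05 in set 1 and 1.12 in set 2) and the myeloid miR-223-3p by −0.36 (−1.06 and 0.29). Several of these values rested on SPF11: without it miR-486a-5p differed by −0.47, miR-92a-3p by −0.33, miR-451a by −0.43, miR-143-3p by −0.54, miR-21a-5p by −0.40, miR-122-5p by 0.02 and miR-223-3p by −0.81. miR-143-3p differed by 0.07 without SPF10 and miR-21a-5p by 0.08 without GF1. limma called 0 of 203 miRNAs, with 7 at unadjusted p under 0.05, of which 6 were higher in GF. edgeR called 0 (5 at unadjusted p under 0.05), and DESeq2 called 1 (7 at unadjusted p under 0.05), miR-16-2-3p, which averaged 1.93 ± 2.71 RPM in GF (SD, n = 16) and 5.65 ± 5.03 RPM in SPF (SD, n = 6).

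Of the erythrocyte miRNAs 7 of 8 were lower in GF, with a median log2 fold change of −0.22. The erythrocyte list was called by camera alone (adjusted p = 0.0381), and the call was lost otherwise (adjusted p = 0.785 with an estimated correlation; adjusted p = 0.779 with fry). The camera call also ended without any 1 of GermFree_Rep2 (adjusted p = 0.101), GermFree_Rep3 (0.169), GermFree_Rep4 (0.0555), GF5 (0.0528), GF7 (0.0567), SPF_Rep1 (0.340), SPF_Rep3 (0.0685) or SPF10 (0.215). In the other lists limma and camera gave no call: 7 of 12 let-7 miRNAs were higher in GF (camera adjusted p = 0.457), 7 of 15 of miR-17-92 (0.305), 0 of 6 platelet and myeloid (0.305), 3 of 5 lymphocyte (0.305), 8 of 10 liver (0.735), 8 of 10 intestinal (0.594) and 4 of 16 known to be carried by HDL (0.134). The smallest p-values in these lists belonged to let-7a-1-3p (0.94), counted together with let-7c-2-3p, miR-25-5p of miR-17-92 (−0.69), miR-181b-5p (0.90) and miR-155-5p (0.68) of lymphocytes, miR-30e-3p of liver (0.40) and the epithelial miR-200a-3p (0.59) and miR-429-3p (0.55), none of which passed. Of these let-7a-1-3p (−0.37) and miR-30e-3p (−0.26) were lower in set 2, and miR-429-3p (−0.31) was lower in set 1.

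Of 48 host tRNAs on HDL 37 had lower values in GF, a count that was not tested, and limma called 0 of the 48, with 3 at unadjusted p under 0.05. Only 24 of the 48 had the same sign in both sets. edgeR and DESeq2 also called 0, with 0 at unadjusted p under 0.05 in each. tRNA-Asn-GTT averaged 9.95 ± 10.4 RPM in GF (SD, n = 16) and 20.9 ± 7.27 RPM in SPF (SD, n = 6), a log2 fold change of −1.73 (limma adjusted p = 0.553), and tRNA-Leu-TAA averaged 1.31 ± 1.65 RPM in GF (SD, n = 16) and 4.31 ± 4.97 RPM in SPF (SD, n = 6). Fragments of tRNA-Gly-GCC, the most abundant, averaged 6534 ± 11348 RPM in GF (SD, n = 16) and 9227 ± 15182 RPM in SPF (SD, n = 6), a log2 fold change of −0.57, and tRNA-Gly-CCC differed by −0.55. Without SPF11 these were −0.05 and −0.13, and without SPF10 −1.16 and −1.01.

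The 3 threonine tRNAs ranked above the other tRNAs of the table in GF (camera adjusted p = 0.00125; adjusted p = 0.0128 with an estimated correlation). Against no change fry gave an adjusted p of 0.264, and limma called 0 of the 3 adjusted over the list alone. tRNA-Thr-AGT differed by 0.84, tRNA-Thr-TGT by 0.55 and tRNA-Thr-CGT by 0.32, and of these tRNA-Thr-TGT and tRNA-Thr-CGT were not higher in set 2 (−0.02 and −0.31). Without SPF_Rep1 the camera call ended (adjusted p = 0.0555), and with an estimated correlation it ended without SPF_Rep1 (adjusted p = 0.136) or SPF10 (adjusted p = 0.0967). The other tRNA lists gave no camera call: all 5 leucine tRNAs were lower (adjusted p = 0.0979), as were the 3 alanine (0.447), 4 serine (0.447), 4 glycine and 3 proline tRNAs (0.763 each). Of the arginine tRNAs 3 of 5 were higher (0.447), and of the valine tRNAs 1 of 3 (0.763). For arginine and valine camera pointed up while the mean log2 fold changes were −0.01 and −0.27, since camera ranks a list against the other tRNAs of its table. For the leucine tRNAs fry gave an adjusted p of 0.0923. The permutation test of their mean log2 value, chosen after seeing the data, gave −0.71 (interval −1.23 to −0.19, two-sided exact p = 0.0108). That exact p was the smallest of the 30 lists, muscle miRNAs included, but adjusted over them it was 0.325.

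Ribosomal, nuclear and nucleolar RNAs of the host on HDL gave no limma call. Of 31 rRNAs limma called 0 (2 at unadjusted p under 0.05, smallest adjusted p = 0.633), whereas edgeR called 2, Gm23918 and n-R5s63, and DESeq2 called Gm23918 (2 at unadjusted p under 0.05 in each). Gm23918 (−1.38) and the 5S rRNA gene n-R5s63 (−1.15) rest on SPF_Rep1, which held 151 and 93.6 RPM. The 28S rRNA averaged 27870 ± 55759 RPM in GF (SD, n = 16) and 16598 ± 13286 RPM in SPF (SD, n = 6), a log2 fold change of −0.15 within sets (0.17 in set 1 and −0.45 in set 2). The GF mean was carried by set 1, with 57775 ± 76870 RPM in GF (SD, n = 7), and the 18S rRNA differed by −0.10. Without GermFree_Rep6, which held 219547 RPM, the 28S rRNA differed by −0.39, and without SPF10 by 0.00. The 18S rRNA differed by −0.34 without SPF11 and 0.04 without SPF12. limma called 0 of 47 snRNAs (0 at unadjusted p under 0.05; edgeR 0 with 3, DESeq2 0 with 1), 0 of 27 snoRNAs (1; edgeR 0 with 4, DESeq2 0 with 2) and 0 of 27 other host RNAs (0; edgeR 0 with 1, DESeq2 0 with 1).

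Among the abundant RNAs of the remaining host classes, the Y RNA Rny1, part of the Ro particle, averaged 305 ± 177 RPM in GF (SD, n = 16) and 263 ± 230 RPM in SPF (SD, n = 6), a log2 fold change of 0.54. Rn7s1, the RNA of the signal recognition particle, which is counted together with Rn7s2, differed by 0.59. Without GermFree_Rep1, which held 5742 RPM, Rn7s1 differed by 0.21, and without SPF10 by 0.10, but without SPF11 by 1.37. The vault RNA Vaultrc5 differed by 0.23 (0.64 in set 1 and −0.15 in set 2), and by −0.36 without SPF_Rep4. The smallest p-values of these tables belonged to Snhg20 (1.36, limma adjusted p = 0.530) and Gm27539 (−0.98) of other host RNA, the snoRNAs Gm23246 (1.13) and Gm23969 (0.69), and the snRNAs Gm24407 (−0.77) and Gm24497 (0.56). The abundant snRNA Rnu11 of the minor spliceosome differed by −0.68 (0.33 in set 1 and −1.62 in set 2) and Gm22317 by −0.65, and the abundant snoRNAs Snord85 by 0.03 (1.16 and −1.02) and Rnu3b1, a U3 RNA, by −0.17. Snord85 differed by −0.29 without SPF_Rep1, and Rnu3b1 by 0.09 without SPF12. The lists of 19 5S rRNAs (12 higher, camera adjusted p = 0.088), 3 U1 snRNAs (0 higher, 0.0521) and 13 C/D snoRNAs (9 higher, 0.903) gave no call.

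Pseudomonas and other water and soil bacteria were among the most abundant bacterial categories over all HDL libraries, where P. fluorescens and P. putida rested on set 2 and S. maltophilia on set 1. Pseudomonas fluorescens averaged 65030 ± 66033 RPM in GF (SD, n = 16) and 56632 ± 78537 RPM in SPF (SD, n = 6), a log2 fold change of 0.40, which was 0.69 without SPF11 (203101 RPM) and 0.25 without SPF_Rep3. Stenotrophomonas maltophilia, found in water and in hospitals, averaged 11680 ± 21665 RPM in GF (SD, n = 16) and 3395 ± 3333 RPM in SPF (SD, n = 6), a log2 fold change of 0.68. In set 1 it averaged 26025 ± 27322 RPM in GF (SD, n = 7) and 6260 ± 1747 RPM in SPF (SD, n = 3). In set 2 it averaged 523 ± 223 RPM in GF (SD, n = 9) and 530 ± 298 RPM in SPF (SD, n = 3). Pseudomonas putida differed by 0.31 (0.82 in set 1 and −0.16 in set 2). In the human-microbiome database Pseudomonas 2 1 26 differed by 0.25 (0.96 and −0.41) and Pelomonas, a genus of purified water, by 0.29. Without GermFree_Rep3 Pelomonas differed by 0.13, and without SPF10 P. putida by 0.13 and Pseudomonas 2 1 26 by 0.05. Listeria innocua, a harmless relative of L. monocytogenes, differed by −0.82 (0.41 in set 1 and −1.97 in set 2). Its values rested on SPF11 (5806 RPM), SPF12 (12143 RPM) and GF1 (27236 RPM). Listeria innocua differed by −0.14 without SPF12 and −0.37 without SPF11, but by −1.40 without SPF10.

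limma called 0 of 207 human-microbiome categories (7 at unadjusted p under 0.05, all higher in GF, smallest adjusted p = 0.911). edgeR called 0 with 7 at unadjusted p under 0.05, and DESeq2 called 0 with 12. Desmospora averaged 218 ± 114 RPM in GF (SD, n = 16) and 109 ± 50.7 RPM in SPF (SD, n = 6), a log2 fold change of 0.89, and Arcobacter butzleri JV22, an intestinal and water bacterium, differed by 0.77. Of 167 environmental categories limma called 0 (2 at unadjusted p under 0.05, smallest adjusted p = 0.809; edgeR 0 with 4, DESeq2 0 with 14), although 139 were higher in GF. The sign was the same in both sets for 61 of the 167, and for 62 of the 207 human-microbiome categories. The environmental class total differed by 0.89 in set 1 and −0.11 in set 2, and the human-microbiome total by 0.43 and −0.31. Without weights the smallest environmental p-values belonged to the fish pathogen Moritella viscosa (0.81) and the sheep pathogen Bibersteinia trehalosi (0.79). With weights per library limma called 51 environmental categories, all higher in GF. Splits of the libraries within sets, run without weights, called up to 111 of them, so chance was not excluded for the 51.

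Gut bacteria were not lower in GF as a list: 27 of 37 gut commensals of the human-microbiome database were higher, beside 143 of all its 207 categories. For the list camera gave an adjusted p of 0.422. Erysipelotrichaceae bacterium 21 3 differed by 0.85 (1.77 in set 1 and −0.01 in set 2) and Eubacterium 3 1 31 by 0.74 (1.58 and −0.05). Skin and oral bacteria were called lower by camera alone (10 of 17 lower, median −0.15, Micrococcus luteus −0.60, adjusted p = 0.00782), and the call was lost otherwise (adjusted p = 0.787 with an estimated correlation; adjusted p = 0.972 with fry). That call also ended without SPF_Rep3 (adjusted p = 0.298) or SPF_Rep4 (adjusted p = 0.0621). The lists of reagent and water bacteria (9 of 14 higher, camera adjusted p = 0.577), Bacteroidetes (4 of 8, 0.506), Firmicutes (14 of 29, 0.0575), Actinobacteria (8 of 15, 0.0711) and Proteobacteria (19 of 23, 0.225) gave no call. In the environmental database reagent and water bacteria (11 of 12 higher), Firmicutes (3 of 3) and Proteobacteria (15 of 16) gave none either (camera adjusted p = 0.9998 each), and camera, which ranks a list against the rest of its table, pointed down for all of them. In the human-microbiome database it pointed down for reagent and water bacteria and for Actinobacteria too, though more of their members were higher than lower.

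**Figure D4:**
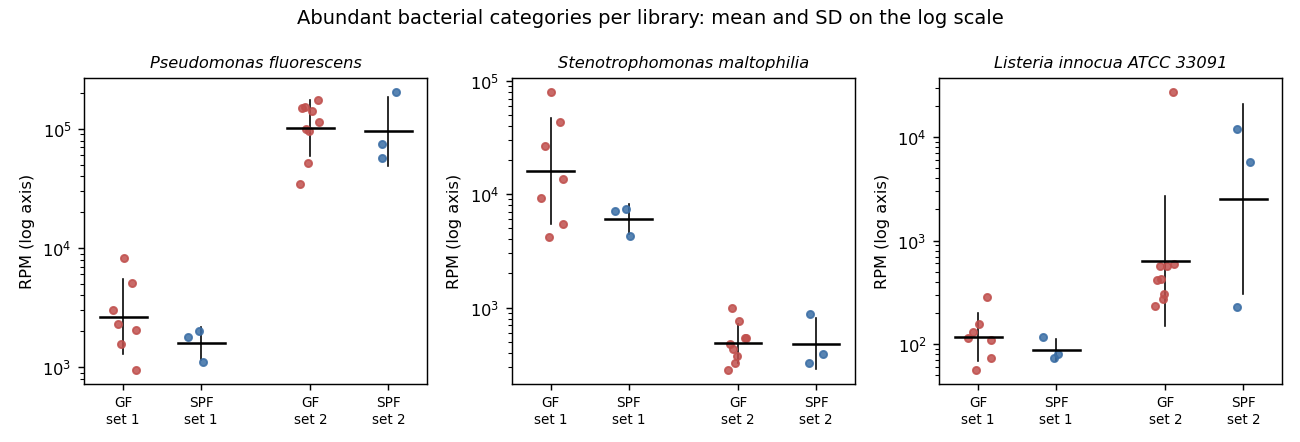
RPM of Pseudomonas fluorescens, Stenotrophomonas maltophilia and Listeria innocua on a log axis, 1 point per library, GF in red and SPF in blue by set. The sets lie further apart than the groups.

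Fungal and algal reads also gave no call between GF and SPF. Histoplasma capsulatum, a soil fungus, averaged 10200 ± 5416 RPM in GF (SD, n = 16) and 7443 ± 5203 RPM in SPF (SD, n = 6), a log2 fold change of 0.44, the yeast Saccharomyces cerevisiae differed by −0.19 and the plant pathogen Fusarium oxysporum by −0.20 (−0.66 in set 1 and 0.22 in set 2), or 0.03 without SPF_Rep4. limma called 0 of 8 fungi and 0 of 35 algae (0 at unadjusted p under 0.05 in each, as with edgeR and DESeq2, which also called 0). Without GermFree_Rep6, GF1 and SPF11, left out after seeing the data, limma called Histoplasma capsulatum (0.70, adjusted p = 0.0476). Among algae, named here by the genome codes of the table, Galsul1 differed by −0.58, Nanoce1779_2 by −0.30 (0.01 in set 1 and −0.58 in set 2), Sobl393_1 by −0.14 and Thaoce1 by −0.01 (0.14 without SPF10).

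Whether the GF effect differed between the sets was also tested, and limma called 0 of the features in all 10 tables. That does not show the effect to be the same in both sets. Of the human-microbiome bacteria 26 had an unadjusted limma p under 0.05 for that term, of the environmental bacteria 9 and of the miRNAs 6. Chance gives about 10.35, 8.35 and 10.15. Of the 119 features followed with each library left out, 92 had a log2 fold change that moved by over 1.5 times or turned its sign without some 1 library, and 26 turned their sign. The fold changes of uncalled features describe these libraries and establish no difference between GF and SPF. For the class totals the test by set was chosen after seeing the data, and the smallest two-sided exact permutation p was 0.153, for viruses (adjusted p = 0.854).

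Host small RNA made up a lower share of the reads in set 2 than in set 1, in GF and SPF alike, a comparison chosen after seeing the data. The share was 11.8 ± 9.49% of reads in GF of set 1 (SD, n = 7) and 1.70 ± 0.761% in GF of set 2 (SD, n = 9), against 9.46 ± 4.83% and 1.71 ± 0.480% in SPF (SD, n = 3 each), a log2 difference between sets of −2.55 (95% interval −3.21 to −1.90, two-sided exact p = 4.4e-06, the smallest the permutations can give). limma called 147 of 203 miRNAs lower in set 2 and 0 higher, 31 of 48 tRNAs lower, and 89 environmental bacteria higher with 22 lower. These balances changed with the scaling: when each value was taken as a share of its own table, limma called 36 miRNAs higher and 43 lower, 1 tRNA higher and 2 lower, and 25 environmental bacteria higher and 69 lower. P. fluorescens averaged 2828 ± 2255 RPM in set 1 (SD, n = 10) and 112666 ± 52831 RPM in set 2 (SD, n = 12), whereas S. maltophilia averaged 20096 ± 24280 RPM in set 1 (SD, n = 10) and 525 ± 229 RPM in set 2 (SD, n = 12). Each set holds both groups, so this difference does not bear on GF against SPF within a set.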

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

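Values far from the rest of their group were screened in SPF (n = 6), GF of set 1 (n = 7) and GF of set 2 (n = 9) for class totals, depth and every named feature. Of 405 groups 44 held such a value, where chance gives about 1 in 20, or 20.2. SPF was screened over both sets together, and some flagged groups held 0 in every other library, so 20.2 is a rough guide. Of the tests in this part, the splits for lists, the scaling of the muscle miRNAs and the summed gut bacteria were set out before their results were seen, and all others were chosen after the result was seen.

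GermFree_Rep6 had the lowest values of GF set 1 for fungi (7980 RPM, others 16337 to 20536), viruses (361 RPM), the ratio of non-host to host reads (0.575, others 2.75 to 6.31), tRNA-Phe-GAA (2.57 RPM), tRNA-Tyr-GTA (3.85 RPM), tRNA-Val-TAC (0.428 RPM), Desmospora (42.8 RPM), Anaerococcus hydrogenalis (12.6 RPM), Campylobacter (29.7 RPM) and Paenibacillus polymyxa (63.3 RPM). GF1 had the highest human-microbiome bacteria of GF set 2 (239340 RPM, others 50934 to 96270), non-host tRNA (156780 RPM), Listeria innocua (27236 RPM, others 230 to 588) and Gm23969 (0.313 RPM), and the lowest miR-486a-5p (115 RPM) and miR-143-3p (17.2 RPM). SPF11 was lowest of SPF for algae (26373 RPM), miR-122-5p (21.03 RPM, others 168 to 452) and tRNA-Asn-GTT (7.46 RPM). SPF_Rep1 was highest of SPF for Gm23918 (151 RPM), n-R5s63 (93.6 RPM), n-R5s101 (1.95 RPM) and Gm22092 (34.3 RPM), SPF_Rep3 for tRNA-Ile-AAT (22.2 RPM) and SPF12 for Paenibacillus polymyxa (380 RPM).

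Other libraries stood highest in GF set 1: GermFree_Rep1 for other host RNA (9573 RPM, others 773 to 1672), tRNA-Lys-TTT (340 RPM) and Rnu5g (13.5 RPM), GermFree_Rep3 for Pelomonas (9248 RPM), GermFree_Rep4 for tRNA-Ser-GCT (79.4 RPM) and Gm22092 (0.444 RPM), GermFree_Rep5 for Corynebacterium accolens (621 RPM) and GermFree_Rep7 for tRNA-Val-AAC (53.2 RPM). In GF set 2, GF7 had the most reads (28685000) and the highest Rnu5g (1.67 RPM), GF8 the highest miR-25-5p (1.53 RPM), miR-144-3p (4.49 RPM) and n-R5s101 (2.69 RPM), GF4 the highest miR-20a-5p (9.17 RPM) and tRNA-Pro-CGG (29.8 RPM), GF5 the highest Gm23918 and n-R5s63 (0.112 RPM each), and GF6 the highest Gm24407 (0.0622 RPM) and Snord118 (1.43 RPM).

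The 4 tested muscle miRNAs had higher values in GF. Of 100 splits of the libraries within sets, the real groups included, 2 gave a mean t at least as far from 0 (2.52 for the real groups, 2.66 at most in the others). The list had the smallest camera p of the 30 tested. By the exact permutation test the leucine tRNAs had a smaller unadjusted p (0.0108 against 0.0235). Adjusted over the 30 lists the exact permutation p of the muscle miRNAs was 0.353, so chance was not excluded. Scaling to all reads of a library was excluded as the whole cause, since scaling within miRNAs left the log2 difference at 1.67 (95% interval 0.35 to 2.99, two-sided exact permutation p = 0.0175) beside 1.65 before. A single library as the cause was left open: the lowest difference, without SPF_Rep4, was still 1.30, but its interval included 0 (−0.14 to 2.74, two-sided exact permutation p = 0.0749, against 0.24 to 3.04 with all libraries), and the camera call with an estimated correlation ended there (adjusted p = 0.102). Muscle RNA carried into some preparations stays open beside a change in GF mice, because these miRNAs, which are made in the same tissue, would vary together under either.

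Bacterial reads were not separated between GF and SPF, though the interval for environmental bacteria reached beyond 2-fold. If the gut flora of SPF mice were the main source, gut commensals would be at least 2-fold lower in GF. Their mean log2 level differed by 0.14 (95% interval −0.32 to 0.59, two-sided exact permutation p = 0.529), so no such fall was seen on average. In that mean rare and abundant categories count alike, so it cannot tell the main source of the reads. Whether these reads come from the genera named was not tested either. The sum of the gut commensals differed by −0.0626 (−1.04 to 0.85) and left the question open. Reagent and water bacteria held 39.2% of the environmental reads in the median SPF library and 53.0% in the median GF library, which cannot tell whether reagents were the source. These medians pool the sets, so they do not compare GF with SPF within a set. Reads also matched several databases, with non-host categories summing to 1.36 to 2.12 times the reads mapped to non-host, so names of single bacteria may stand for shared sequence.

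Host small RNA had a lower share in set 2, in GF (log2 −2.61) and in SPF (−2.38) alike. Dilution by reads mapped to non-host was excluded as the whole cause, since the difference stayed at −2.34 (95% interval −2.98 to −1.71, two-sided exact p = 4.4e-06, the smallest the permutations can give) once these were left out of the total. Unmapped reads stayed in that total. They cannot alter the ratio of non-host to host reads, which was higher in set 2 by a log2 difference of 2.99 (two-sided exact p = 4.4e-06). In SPF the unmapped share was 55.0 ± 3.26% in set 1 and 48.6 ± 5.39% in set 2, whereas in GF it rose from 42.9 ± 7.29% to 56.4 ± 4.05%. The ratio and the SPF shares argue against dilution by unmapped reads alone. Dilution by non-host and unmapped reads together would raise the ratio too, was not tested and stays open. Loss of 1 kind of host RNA was excluded, because all 6 host classes fell, by 1.76 to 2.80, a range of 1.04 on the log2 scale. Each set held 1 naming pattern and 1 apparent cohort, so different mice and different handling cannot be told apart, and no biological explanation was tested.

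Splits of the libraries within sets, 100 with the real groups included, gave as many calls as the real groups in 100 of 100 for each of the 10 tables, which says nothing about chance, since the real count was 0 and every split had to reach it. The highest count in a split was 24 miRNAs, 1 tRNA, 6 rRNAs, 12 snRNAs, 1 snoRNA, 3 other host RNAs, 42 human-microbiome bacteria, 111 environmental bacteria, 7 fungi and 19 algae. For a set-dependent GF effect the real count was 0 as well, so 100 of 100 splits had to reach it (331 calls at most). For calls between the sets only the real sets did, 1 of 100 (488 calls, 287 at most in the others). Lists called by camera numbered 4, and 37 of 100 splits called as many (9 at most). For single lists a mean t as far from 0 came in 8 of 100 splits for threonine tRNAs, 54 for skin and oral bacteria and 40 for erythrocyte miRNAs. Chance splits were thus not excluded for these, nor for the muscle miRNAs once adjusted over the 30 lists.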

How the results depend on the processing

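Libraries left out as standing apart, each set alone for lists, edgeR and DESeq2 on estimated reads and all settings of the comparison between sets were chosen after seeing the data. Calls between GF and SPF were 0 in 348 of 356 fits over the 10 tables and their alternatives, and class totals and the ratio had no call in 458 of 458. The others gave 1 rRNA (n-R5s41) and 1 snRNA (Gm24407) in set 2 only, 51 environmental bacteria with library weights, 1 fungus (Histoplasma capsulatum) without GermFree_Rep6, GF1 and SPF11, 2 rRNAs with edgeR, and 1 rRNA and 1 miRNA with DESeq2; the cause was not tested. Leaving out each library gave 0 to 1 miRNA calls, the 1 (miR-206-3p) without SPF_Rep3. Set-dependent effects numbered 6 with no filter and 0 to 2 with each SPF library left out (2 without SPF_Rep3). Lists called numbered 4, and 2 with an estimated correlation, 0 with fry, 7 as share of the table, 9 without GermFree_Rep6, GF1 and SPF11, 7 in set 1 only, 1 in set 2 only, and 2 (without SPF_Rep3) to 8 (without SPF11) with each library left out. Calls between the sets as share of the table were 79 miRNAs, 3 tRNAs, 6 rRNAs, 7 snoRNAs, 8 other host RNAs, 0 fungi and 30 algae, against 147, 31, 18, 17, 14, 5 and 16 in RPM, and in GF libraries only 61 human-microbiome bacteria, 73 environmental bacteria and 2 fungi, against 93, 111 and 5. With values as share of the table, 36 miRNAs were higher and 43 lower in set 2 (0 and 147 in RPM), 23 human-microbiome bacteria higher and 45 lower (81 and 12 in RPM), and 25 environmental bacteria higher and 69 lower (89 and 22 in RPM), so for bacteria the balance turned over. The planned count tests on whole reads were run on estimated reads instead. Each library came from its own mouse per the labels, so the design held no pairs. The fewest miRNA reads in a library were 19730, and whether depth limited the calls was not tested.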

Other observations

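On the RPM scale single miRNAs and bacteria differed between the sets to very different degrees, a comparison and a choice of names made after the values were seen. miR-144-3p, which is made in red cells from the same transcript as miR-451a, was lower in set 2 by a log2 difference of −4.87 and miR-30e-5p by −4.65 in limma. The liver miRNA miR-122-5p differed by −0.64 and the myeloid miR-223-3p by −0.37, and neither passed in limma. miR-2137 had the largest difference, −6.01, from 225 ± 248 RPM in set 1 (SD, n = 10) to 2.26 ± 3.18 RPM in set 2 (SD, n = 12).

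Among bacteria, Xanthomonas campestris, a relative of S. maltophilia, was lower in set 2 by −3.82, and the soil bacterium Azotobacter chroococcum, a relative of Pseudomonas, was higher by 3.53. The gut category Ruminococcus was higher in set 2 by 3.61, and Methylobacterium, a genus of tap water and reagents, lower by −1.97. Each of these passed in limma adjusted over its table.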
